A study of Drosophila melanogaster with 12 samples.

How the data were processed

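RNA was measured in wings of female Drosophila melanogaster raised at 25 degrees, in 8 libraries that form 4 groups of 2: wild type and EcR-RNAi, each at -6 h and at +6 h relative to puparium formation. Per the labels, wings at -6 h came from wandering larvae and those at +6 h from animals staged at the white prepupa. In the EcR-RNAi animals a Gal4 system drives a hairpin against EcR, the nuclear receptor for the steroid hormone ecdysone, together with GFP. Wild type and EcR-RNAi also differ in strain background and transgenes, so an effect of the background cannot be told apart from an effect of EcR loss. The other 4 libraries are CUT&RUN libraries, in which an antibody against FLAG directs cleavage of DNA around the tagged EcR protein of an EcR[GFSTF] allele, with 2 libraries per stage. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

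The RNA table holds normalized counts, a signal that the authors made by dividing the read count of each gene by a size factor per library, as the deposited values show. The submitters' processing notes list STAR 2.5.2b, SAMtools 1.3.1, Subread 1.24.2 and DESeq2 1.14.1 and the fly genome build dm3, without roles or settings. Strand handling of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain. So are genes that share reads with a close copy, such as the Jon65A, Ccp84A, Lcp, Lsp1 and Hsp70 genes and the pair Act57B and Act87E. A second table of the authors holds their own comparisons, with a log2 fold change, a p-value and an adjusted p-value per gene, and a test statistic, a score that was not used here. The deposited peak lists give each peak a position in dm3, a score, a fold enrichment as a ratio over background, and -log10 values of p and q. For CUT&RUN the submitters' processing notes list Bowtie2 2.2.8, SAMtools 1.3.1, Picard 2.2.4, bedtools 2.25.0 and MACS2 2.1.1.20160309. Peak names say that the authors merged the replicates of a stage before peaks were called, so replicates cannot be compared for peaks. Score and fold enrichment are the authors' values for a peak and were used only within a list.

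In each RNA column the values are whole multiples of the worth of 1 read, from which whole reads were recovered for 100% of values (tolerance 0.1 read). Recovered depth lay between 6444939 reads (EcR-RNAi at +6 h, replicate 1) and 10016236 reads (wild type at -6 h, replicate 2). The table lists 15240 genes, of which 3291 had no read in any library. Of the symbols, 11814 match a current symbol of the reference annotation, 3310 match a synonym and 116 match neither, and symbols are printed as the table gives them. Replicates differed by more than sampling noise: chi-square per degree of freedom was 11.4 in wild type at -6 h, 18.4 in wild type at +6 h, 32.1 in EcR-RNAi at -6 h and 6.85 in EcR-RNAi at +6 h. Each library was treated as a sample, which this spread alone does not justify.

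Genes with a mean of at least 10 normalized counts over the 8 libraries, 7775 genes, were tested with limma 3.58.1 in R 4.3.3, with trend and robust settings, on log2(normalized count + 1). A model of the 4 group means was fitted to all 8 libraries, which share an estimate of the spread. The comparisons were +6 h minus -6 h in each genotype, EcR-RNAi minus wild type at each stage, and the genotype by stage interaction, which is the stage response in EcR-RNAi minus that in wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and padj stands for an adjusted p. Where a call ended in at least 1 alternative, "lost at padj" gives the highest adjusted p among the alternatives, which include edgeR and DESeq2. Fold changes are on the log2(normalized count + 1) scale, which understates changes of genes with low counts, and the value after ± is the standard error for a log2 fold change and the standard deviation for a level (n = 2 libraries). Where all libraries of a group had 0 reads, a fold was computed against a floor of 3 reads over the group. With 1 to 3 reads a ratio of reads scaled by depth is given with its exact Clopper-Pearson interval (95%). Intervals and floors cover counting error only. The fit was tested on simulated counts with 200 changed genes among 7775. It recovered 77.6% of 2-fold changes in the wild-type stage response, 80.6% in the EcR-RNAi stage response, 71.6% and 85.1% in the genotype comparisons at -6 h and +6 h, and 47.8% in the interaction, with false shares of 11.1%, 6.71%, 5.34%, 7.01% and 6.52% among the calls.

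The design fixed 28 gene lists: ecdysone-response transcription factors and early genes, other ecdysone-inducible genes, small heat shock and chaperone genes, wing patterning and growth, Notch pathway and sensory organ genes, cell cycle and DNA replication, cuticle and chitin, apical matrix and zona pellucida domain proteins, extracellular matrix with integrins and proteases, actomyosin and cell junctions, planar cell polarity, glycolysis, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, autophagy and cell death, melanin with pigment and sclerotization, antimicrobial peptides and immune genes, RNA interference machinery, JNK and regeneration-type stress, adult muscle precursors, tracheal cells, haemocytes, fat body, neurons, striated muscle, other discs, X dosage compensation in males, and transgene and background markers. Some genes stand in more than 1 list. Members called were counted with the adjustment over all genes and over the list alone. The 27 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01 and with an estimated correlation, and fry was run beside it.

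The named genes are EcR, the 6 genes with the largest called change in each direction (mean of at least 50 in the higher group, no overlap between the libraries of the groups, unnamed CG and CR genes skipped), called members of the ecdysone list (up to 12 with the lowest p), its members not called, the called members with the lowest p of every other list with at least 3 called members, and the member with the highest mean of each list of other cell types or markers. The rule allowed 2 to 4 members for those other lists. The narrower choice of at most 2, and of leaving out ecdysone list members not called in the EcR-RNAi stage response and the interaction, was made after the values were seen, to limit the length and in part to keep values near 0, whose sign changes easily, out of the text.

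Overlaps of calls between comparisons are set beside the number that independent lists would share. Comparisons with a common group share its chance values, so 20 simulations of unchanged groups against the same libraries give the correlation and covariance that sharing alone produces. For overlaps and correlations the shared group was not split. Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp, with Wilson intervals for shares, 1000 circular shifts of a list along each chromosome arm, and two-sided permutation tests of differences in medians with 100000 resamples. Positions are 1-based. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The annotation at hand is of a later genome release than dm3, so no genes were assigned to peaks, and peaks near changed genes and the EcR motif in peaks were not analysed here.

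Groups, comparisons, lists and these alternatives were fixed before the data were examined: pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, scaling by upper quartile, by a trimmed mean of log ratios (TMM-like) and by quantiles, a term for the replicate number, the 4 libraries of a comparison alone, limma without trend and robust settings, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fold change of at least 2, leaving out each library in turn, other overlap rules and score limits for peaks. Leaving out both libraries with raised roX1 and the circular shift of peaks were added after the data were seen.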

Results

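RNA levels were measured in fly wings before and after puparium formation, in wild type and in wings with RNAi against the ecdysone receptor EcR, and EcR binding was mapped by CUT&RUN at both stages. Pulses of ecdysone time these stages. The comparisons ask how the wing changes from -6 h to +6 h, what differs when EcR is reduced, and where EcR binds. The main component of the log2 values held 67.4% of the variance. It placed wild type at -63.6 and -65.1 at -6 h and at 77.1 and 70.1 at +6 h. EcR-RNAi stood at -44.0 and -29.5, then at 27.9 and 27.1. Replicates correlated with r of 0.982 to 0.991 across genes. In wild type at +6 h the gene Osi7 alone took 5.60% and 4.58% of reads.

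EcR, the target of the RNAi, was at 2194 and 1924 normalized counts in wild type at -6 h and at 5764 and 6852 at +6 h. In EcR-RNAi it was at 1634 and 1307, then at 2201 and 2081. At +6 h the log2 fold change between genotypes was -1.55 ± 0.14, limma padj = 1.0e-05. At -6 h it was -0.49 ± 0.14, limma padj = 0.0449, lost at padj = 0.24. This call ended without either EcR-RNAi library at +6 h, either wild-type library at -6 h or replicate 2 of EcR-RNAi at -6 h, with the 4 libraries of the comparison alone, and with limma without trend and robust settings. EcR rose with stage in wild type (1.61 ± 0.14, limma padj = 2.4e-06) and in EcR-RNAi (0.55 ± 0.14, padj = 0.0196, lost at padj = 0.152), with an interaction of -1.06 ± 0.20, padj = 0.00234. The reads do not separate cells with and without the hairpin.

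**Figure D1:**
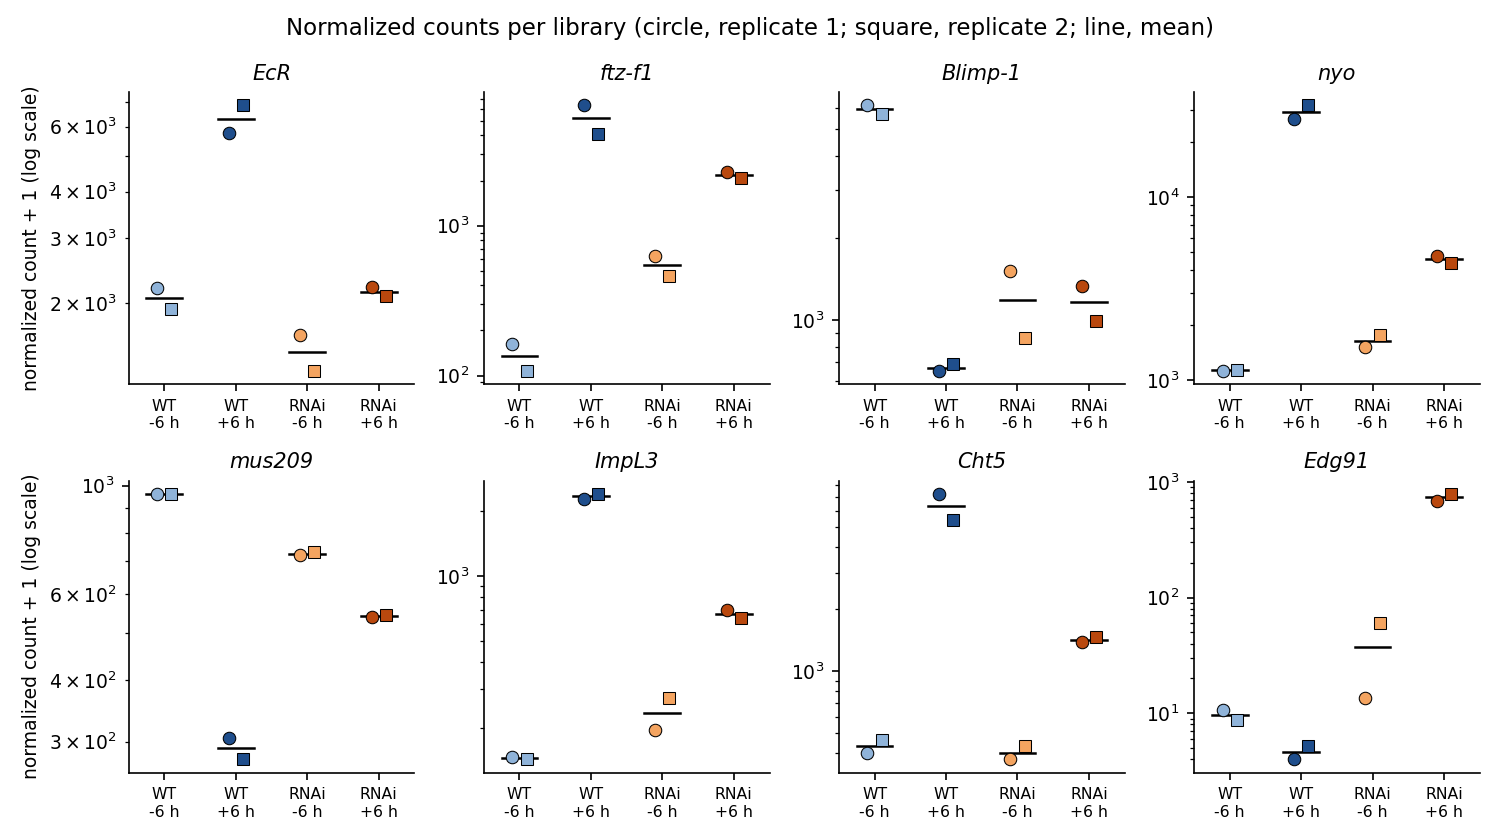
Normalized counts plus 1 on a log axis for EcR, ftz-f1, Blimp-1, nyo, mus209, ImpL3, Cht5 and Edg91 in the 8 RNA libraries, with circles for replicate 1, squares for replicate 2 and lines for the mean of each group (wild type and EcR-RNAi at -6 h and +6 h). EcR reached 6308 in wild type and 2141 in EcR-RNAi at +6 h, and Edg91 3.59 and 735.

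In wild-type wings, 11 of 14 apical matrix, 35 of 57 cuticle, 11 of 12 glycolysis and 15 of 19 extracellular matrix genes rose between -6 h and +6 h, and 35 of 39 cell cycle genes fell. Camera called these lists with the preset correlation but not with an estimated one. The largest increases were those of tx, a basic helix-loop-helix factor gene (9.84 ± 0.25, limma padj = 1.1e-09), and ImpL1, an ecdysone-inducible disc gene (9.71 ± 0.31, padj = 8.5e-07). Next were the cuticle gene TwdlC (9.63 ± 1.199, limma padj = 0.00269), the Osiris family genes Osi7 (9.58 ± 0.45, padj = 1.2e-05) and Osi6 (9.41 ± 0.73, padj = 4.5e-04), and ect (9.48 ± 0.27, padj = 1.1e-07). Osi7 went from 671 ± 97 to 514718 ± 80231 normalized counts and tx from 2.89 ± 1.35 to 3459.9 ± 27.6 (n = 2 each). The largest decreases were those of the cuticle gene Cpr64Aa (-5.44 ± 0.40, limma padj = 6.6e-07), the disc growth factor gene Idgf4 (-3.95 ± 0.12, padj = 4.6e-10) and the aquaporin gene Drip (-3.80 ± 0.27, padj = 8.8e-07). They were followed by fru (-3.64 ± 0.35, limma padj = 2.8e-04), the repressor gene Blimp-1 (-3.14 ± 0.27, padj = 7.2e-05) and the collagen gene mp (-3.14 ± 0.19, padj = 1.7e-07). In all, 2259 of 7775 genes rose and 2075 fell (55.7% together). Of the calls, 52.1% were increases, against 32.3% with upper-quartile and 36.0% with quantile scaling, which shifted the median of all genes by -0.31 and -0.21. TwdlC was at 8.79 without replicate 1 and 10.47 without replicate 2 at +6 h, and at 10.41 and 8.84 without replicates 1 and 2 at -6 h.

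Of 23 ecdysone-response transcription factors and early genes tested, 10 rose and 6 fell (10 and 6 adjusted over the list alone). Their median of 0.39 had a camera padj = 0.343. The median turned to -0.53 with quantile scaling. Increases included Cyp18a1, an ecdysteroid-inactivating enzyme gene (6.25 ± 0.34, limma padj = 1.1e-05), the nuclear receptor gene ftz-f1 (5.27 ± 0.29, padj = 1.2e-05) and Eip93F (3.85 ± 0.32, padj = 7.8e-06). The ABC transporter gene E23 (3.69 ± 0.11, limma padj = 4.6e-10) and the bZIP factor gene vri (3.10 ± 0.18, padj = 4.3e-07) rose too. So did the receptor genes Hr46 (0.91 ± 0.13, limma padj = 8.8e-05), Hr4 (0.86 ± 0.13, padj = 1.3e-04, lost at padj = 0.0819) and usp, the partner of EcR (0.76 ± 0.11, padj = 1.8e-04). The zinc finger gene Kr-h1 (-1.73 ± 0.13, limma padj = 8.4e-07) and the microRNA locus let-7-C (-1.93 ± 0.19, padj = 7.1e-06) fell. Not called by limma were br at 0.39 ± 0.21, Eip75B at 0.01 ± 0.12 and Hr38 at 1.144 ± 0.51, all negative with quantile scaling. There br (limma padj = 0.0187) and Eip75B (padj = 2.8e-04) were called lower, Eip75B also with upper-quartile scaling (padj = 0.0457). The same holds, without that change of sign, for Eip74EF at -0.06 ± 0.12, Eip78C at -0.20 ± 0.14, tai at -0.16 ± 0.15 and Smr at -0.08 ± 0.16, all called lower with upper-quartile and quantile scaling. In other alternatives br (lowest padj = 0.0301) and Hr38 (0.0115) were called higher. Of 14 other ecdysone-inducible genes tested, 9 rose and 1 fell (9 and 1 adjusted over the list alone). Their median of 1.16 had a camera padj = 0.00719 (adjusted p = 0.347 with an estimated correlation). Among them were ImpL3, a lactate dehydrogenase gene (4.01 ± 0.14, limma padj = 2.4e-09), and the transmembrane protease gene Sb (3.37 ± 0.13, padj = 3.6e-09).

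Of 14 apical matrix and zona pellucida domain genes tested, 11 rose and 2 fell (11 and 2 adjusted over the list alone). Their median of 3.99 had a camera padj = 7.2e-05 (adjusted p = 0.132 with an estimated correlation). The zona pellucida domain gene nyo went from 1127 ± 13 to 29139 ± 3637 normalized counts (n = 2 each). Its log2 fold change was 4.69 ± 0.13, limma padj = 3.4e-10, and that of f, the gene for the actin bundler Forked, was 4.55 ± 0.13, padj = 4.1e-10. Of 57 cuticle and chitin genes tested, 35 rose and 4 fell (37 and 5 adjusted over the list alone). Their median of 1.88 had a camera padj = 4.1e-05 (adjusted p = 0.675 with an estimated correlation). The chitinase gene Cht5 rose (3.86 ± 0.15, limma padj = 3.8e-09). Of 19 extracellular matrix, integrin and protease genes tested, 15 rose and 1 fell (16 and 1 adjusted over the list alone). Their median of 0.95 had a camera padj = 4.6e-05 (adjusted p = 0.132 with an estimated correlation). The protease gene Np led (3.84 ± 0.14, limma padj = 2.2e-09). Of 12 glycolysis genes tested, 11 rose and 0 fell (11 and 0 adjusted over the list alone). Their median of 1.52 had a camera padj = 2.8e-05 (adjusted p = 0.347 with an estimated correlation). Pglym78, a phosphoglycerate mutase gene, was at 2.12 ± 0.13, limma padj = 1.6e-07. Of 10 melanin, pigment and sclerotization genes tested, 6 rose and 1 fell (7 and 1 adjusted over the list alone). Their median of 1.22 had a camera padj = 0.0574. The oxidase gene laccase2 (3.10 ± 0.11, limma padj = 1.7e-09) and ple, the tyrosine hydroxylase gene (5.90 ± 0.22, padj = 2.8e-08), rose. Of 11 JNK and stress genes tested, 7 rose and 0 fell (8 and 0 adjusted over the list alone). Their median of 0.45 had a camera padj = 0.0209 (adjusted p = 0.347 with an estimated correlation). They included the JNK phosphatase gene puc (1.60 ± 0.10, limma padj = 2.1e-07) and the TNF gene egr (2.85 ± 0.26, padj = 1.0e-05).

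Of 39 cell cycle and DNA replication genes tested, 1 rose and 35 fell (1 and 35 adjusted over the list alone). Their median of -1.44 had a camera padj = 6.7e-11 (adjusted p = 0.136 with an estimated correlation). The mitotic activator gene fzy fell (-2.21 ± 0.12, limma padj = 4.7e-08), as did mus209, the PCNA gene (-1.73 ± 0.10, padj = 1.0e-07). Of 72 mitochondrial ribosomal protein genes tested, 2 rose and 27 fell (2 and 26 adjusted over the list alone). Their median of -0.40 had a camera padj = 2.2e-04 (adjusted p = 0.347 with an estimated correlation). Of 87 cytosolic ribosomal protein genes tested, 25 rose and 3 fell (7 and 3 adjusted over the list alone). Their median of 0.29 had a camera padj = 0.0243 (adjusted p = 0.802 with an estimated correlation). That median turned negative with upper-quartile and quantile scaling, and RpLP0-like (-1.43 ± 0.15, limma padj = 9.7e-06) and RpL24-like (-0.83 ± 0.11, padj = 6.8e-05) fell. Of 35 wing patterning and growth genes tested, 3 rose and 12 fell (3 and 12 adjusted over the list alone). Their median of -0.27 had a camera padj = 0.0574. The transcription factor gene kn rose (1.31 ± 0.14, limma padj = 1.7e-05) and ap fell (-0.91 ± 0.12, padj = 8.5e-05). Of 8 small heat shock and chaperone genes tested, 3 rose and 4 fell (3 and 4 adjusted over the list alone). Their median of -0.07 had a camera padj = 0.825. Hsc70-3 rose (1.62 ± 0.15, limma padj = 3.6e-06) and Hsp27 fell (-1.38 ± 0.13, padj = 5.1e-06). Of 20 Notch pathway and sensory organ genes tested, 9 rose and 5 fell (9 and 5 adjusted over the list alone). Their median of 0.35 had a camera padj = 0.596. The ligand gene Ser fell (-0.92 ± 0.10, limma padj = 1.0e-05) and E(spl)m7-HLH rose (1.098 ± 0.12, padj = 1.6e-05), and the median turned negative with quantile scaling.

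The lists in this paragraph did not pass camera in wild type or, for immune genes, were not tested. Of 26 actomyosin and junction genes tested, 7 rose and 1 fell (6 and 1 adjusted over the list alone). The median of 0.13 turned negative with upper-quartile and quantile scaling, and the myosin light chain gene sqh (1.03 ± 0.13, limma padj = 4.4e-05) and ed (1.27 ± 0.17, padj = 7.6e-05) rose. Of 10 planar cell polarity genes tested, 2 rose and 2 fell (2 and 1 adjusted over the list alone). The median was -0.12, with pk at -1.16 ± 0.11, limma padj = 4.1e-06 and dgo at 0.66 ± 0.13, padj = 0.00148. Of 19 autophagy and cell death genes tested, 5 rose and 1 fell (5 and 1 adjusted over the list alone). The median of 0.13 turned negative with upper-quartile and quantile scaling, and the apoptosis inhibitor gene th (1.15 ± 0.10, limma padj = 3.8e-06) and the death gene rpr (1.82 ± 0.18, padj = 1.4e-05) rose. Of 7 RNA interference genes tested, 1 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.32, with Dcr-2 at -1.13 ± 0.13, limma padj = 1.8e-05 and Dcr-1 at -0.83 ± 0.13, padj = 3.0e-04. Only 2 of 21 antimicrobial peptide and immune genes could be tested, and both rose (2 adjusted over the list alone).

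In EcR-RNAi wings, 27 of 57 cuticle, 10 of 14 apical matrix and 11 of 23 ecdysone-response genes rose between -6 h and +6 h, and 2 of 8 fat body genes fell. These lists, too, passed camera only with the preset correlation. The largest increases included lmd, a myoblast factor gene with 2 reads at -6 h and a ratio of 293 (95% counting interval 80.6 to 2425). The phagocytic receptor gene nimC4 had no read at -6 h and was at least 43.9-fold higher at +6 h. Cuticle genes rose, namely Edg84A (5.93 ± 1.19, limma padj = 0.0413, lost at padj = 0.188), Ccp84Ab (4.94 ± 1.04, padj = 0.0295, lost at padj = 0.178), Edg91 (4.67 ± 0.61, padj = 0.00151, lost at padj = 0.116) and Ccp84Ad (4.63 ± 0.99, padj = 0.0375, lost at padj = 0.176). The gut protease genes Jon65Aiv, yip7 and Jon25Bi had no read at +6 h and were at least 196-fold, 108-fold and 50.7-fold lower. The calls of Jon65Aiv (lost at padj = 0.11) and Jon25Bi (lost at padj = 0.129) ended with edgeR. Jon65Aiii, with 1 read at +6 h, had a ratio of 502 (95% counting interval 89.7 to 19842) for -6 h over +6 h, and Nplp4, with 3 reads, one of 42 (95% counting interval 14.1 to 206). The prophenoloxidase gene proPO45 fell (-4.97 ± 0.63, limma padj = 3.5e-04). In all, 943 genes rose and 302 fell (16.0% of those tested). Of the calls, 75.7% were increases, against 46.9% with upper-quartile and 45.3% with quantile scaling, each of which shifted the median of all genes by -0.13. Decreases numbered 874 and 945 under those scalings, 182 with DESeq2, 96 or 99 without replicate 2 or 1 of EcR-RNAi at +6 h and 161 without its replicate 1 at -6 h. Increases numbered 506 or 521 without replicate 2 or 1 of EcR-RNAi at +6 h. Without replicates 1 and 2 of EcR-RNAi at -6 h, Edg84A was at 4.21 and 7.65, Ccp84Ab at 3.81 and 6.07, Edg91 at 3.59 and 5.75, and Ccp84Ad at 3.32 and 5.95. In the same order the log2 fold changes were -7.09 and -8.997 for Jon65Aiv, -6.62 and -8.01 for yip7, -6.24 and -8.29 for Jon65Aiii and -4.77 and -7.14 for Jon25Bi, and nimC4 was at 6.39 and 5.15 without replicates 1 and 2 at +6 h.

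Of 23 ecdysone-response transcription factors and early genes tested, 11 rose and 1 fell (11 and 1 adjusted over the list alone). Their median of 0.41 had a camera padj = 9.4e-05 (adjusted p = 0.44 with an estimated correlation). They included Cyp18a1 (3.09 ± 0.34, limma padj = 0.00175), Eip93F (2.75 ± 0.32, padj = 4.1e-04), Hr46 (2.23 ± 0.13, padj = 9.7e-07) and ftz-f1 (2.01 ± 0.29, padj = 0.00569). E23 (1.43 ± 0.11, limma padj = 8.8e-06), vri (1.18 ± 0.18, padj = 0.00173) and Hr4 (0.89 ± 0.13, padj = 5.9e-04) rose, and Kr-h1 fell (-0.69 ± 0.13, padj = 0.00428, lost at padj = 0.0692). Eip75B (0.56 ± 0.12, limma padj = 0.0105, lost at padj = 0.108), Hr39 (0.41 ± 0.12, padj = 0.0443, lost at padj = 0.208) and Hr38 (1.68 ± 0.51, padj = 0.0479, lost at padj = 0.244) were called with less margin. Of 14 other ecdysone-inducible genes tested, 7 rose and 1 fell (8 and 1 adjusted over the list alone). Their median of 0.49 had a camera padj = 0.00203 (adjusted p = 0.261 with an estimated correlation). ImpE1 (1.75 ± 0.14, limma padj = 1.1e-05) and Sb (1.52 ± 0.13, padj = 1.7e-05) rose. Of 57 cuticle and chitin genes tested, 27 rose and 4 fell (44 and 4 adjusted over the list alone). Their median of 2.18 had a camera padj = 2.2e-13 (adjusted p = 0.44 with an estimated correlation). Cht5 rose (1.82 ± 0.15, limma padj = 1.3e-05) and Idgf4 fell (-2.45 ± 0.12, padj = 4.1e-07). Of 14 apical matrix genes tested, 10 rose and 1 fell (10 and 1 adjusted over the list alone). Their median of 1.33 had a camera padj = 2.1e-05 (adjusted p = 0.198 with an estimated correlation). The zona pellucida domain genes m (2.19 ± 0.14, limma padj = 3.0e-06) and tyn (1.69 ± 0.14, padj = 1.7e-05) rose.

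Of 39 cell cycle genes tested, 0 rose and 7 fell (0 and 8 adjusted over the list alone). Their median of -0.30 had a camera padj = 1.6e-06 (adjusted p = 0.261 with an estimated correlation). The Aurora B gene ial (-0.59 ± 0.13, limma padj = 0.0128, lost at padj = 0.0982) and the spindle checkpoint gene BubR1 (-0.51 ± 0.12, padj = 0.0132, lost at padj = 0.113) fell. Of 8 small heat shock and chaperone genes tested, 1 rose and 3 fell (1 and 4 adjusted over the list alone). Their median of -0.41 had a camera padj = 0.0036 (adjusted p = 0.44 with an estimated correlation). Hsp68 fell (-4.32 ± 0.18, limma padj = 3.2e-07) and Hsc70-3 rose (0.68 ± 0.15, padj = 0.00899, lost at padj = 0.0967). Camera also called extracellular matrix (8 of 19 higher, 1 lower, median 0.22, camera padj = 0.00412), melanin and sclerotization (4 of 10 higher, 0 lower, median 0.85, camera padj = 0.00412), glycolysis (3 of 12 higher, 0 lower, median 0.22, camera padj = 0.0201), wing patterning (1 of 35 higher, 2 lower, median -0.13, camera padj = 0.00988) and mitochondrial ribosomal genes (0 of 72 higher, 0 lower, median -0.16, camera padj = 0.00203). With an estimated correlation they had adjusted p = 0.261 to 0.541, and 9, 5, 3, 1 and 0 members were higher and 1, 1, 0, 1 and 0 lower adjusted over the list alone. Among the members, the metalloprotease gene Mmp2 (0.98 ± 0.11, limma padj = 8.8e-05), ple (4.17 ± 0.22, padj = 3.1e-06), ImpL3 (1.54 ± 0.14, padj = 3.5e-05) and Ald, an aldolase gene (0.59 ± 0.15, padj = 0.0179, lost at padj = 0.149), rose. The signalling gene wg fell (-0.45 ± 0.11, limma padj = 0.0191, lost at padj = 0.18).

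The interaction compared the stage responses directly. It was negative for 10 of 14 apical matrix, 13 of 19 extracellular matrix and 10 of 12 glycolysis genes, lists whose median increase was smaller in EcR-RNAi, and positive for 26 of 39 cell cycle genes, whose median decrease was smaller. Camera called none of them with an estimated correlation. In all, it was negative for 1197 genes and positive for 905 (27.04% of those tested). Of the 2259 genes that rose in wild type, 1174 (52.0%) had a negative interaction, and of the 2075 that fell, 879 (42.4%) had a positive one. The interaction shares the wild-type libraries, and in 20 simulations with the wild-type response in both genotypes at most 1 gene did either. For 6 genes the response in EcR-RNAi was larger in the same direction, and for 2275 the interaction was not called. Over the 4334 genes called in wild type, the slope of the EcR-RNAi response on the wild-type response was 0.41 (r = 0.86 and rho = 0.84 across genes), against a mean of 0.97 in these simulations. It was 0.47 for genes that rose, 0.30 for genes that fell and 0.42 for all genes tested. Of the calls, 43.1% were positive, against 60.6% with upper-quartile scaling, which shifted the median of all genes by 0.17 and gave 1377 positive calls, and 54.2% with quantile scaling. Without replicate 2 of EcR-RNAi at +6 h, 584 interactions were positive.

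**Figure D2:**
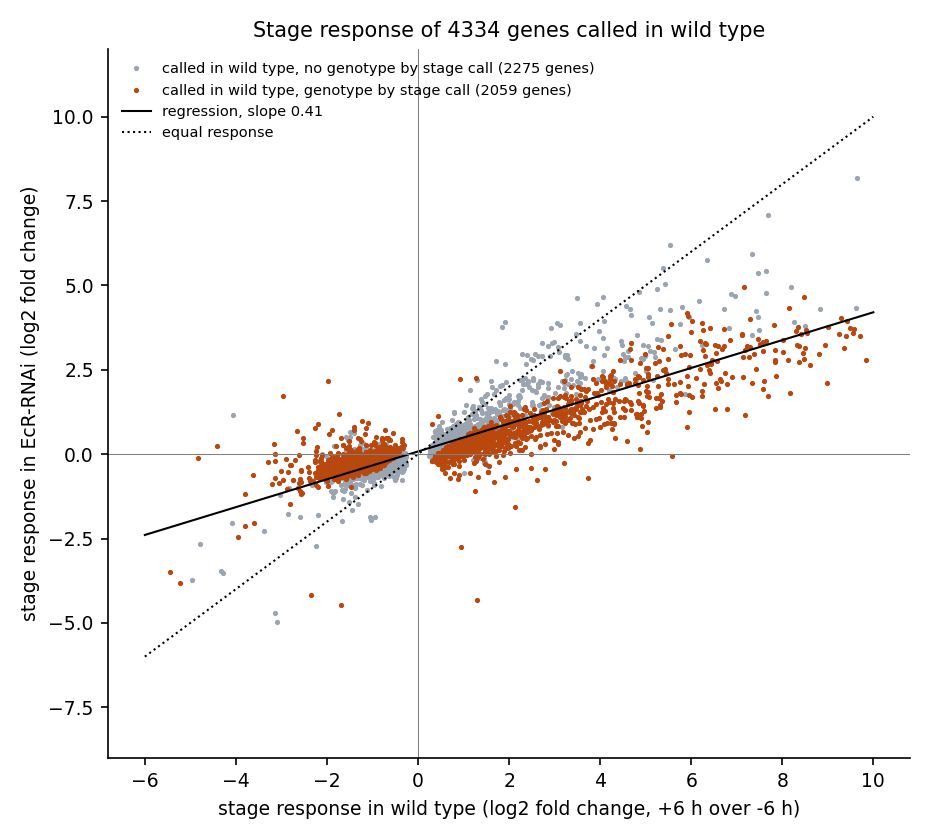
Stage response (log2 fold change, +6 h over -6 h) in EcR-RNAi on the vertical axis against wild type on the horizontal axis for the 4334 genes called in wild type, with orange points for the 2059 genes with a genotype by stage call and grey points for the 2275 without. The solid line is the regression with a slope of 0.41 and the dotted line marks an equal response.

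The most negative interactions were those of Jon65Aiii (-8.76), tx (-7.06 ± 0.35, limma padj = 1.2e-06), yip7 (-6.84), Jon65Aiv (-6.67), ImpL1 (-6.19 ± 0.44, padj = 1.7e-04) and Osi3 (-6.03 ± 0.63, padj = 5.6e-05). The fitted values of the 3 protease genes depend on the pseudocount, as each group other than EcR-RNAi at -6 h had 0 to 5 reads of each, and their calls ended with edgeR (adjusted p = 0.178 for Jon65Aiii, 0.292 for yip7 and 1 for Jon65Aiv). The most positive were those of Edg91 (5.75 ± 0.86, limma padj = 0.00207), the aldehyde dehydrogenase gene Aldh (4.16 ± 0.54, padj = 0.0011) and Blimp-1 (3.16 ± 0.38, padj = 0.00141). Next were fru (3.03 ± 0.49, limma padj = 0.0073), mp (2.93 ± 0.27, padj = 2.8e-05) and the lipoprotein receptor gene LRP1 (2.75 ± 0.16, padj = 9.7e-07). Blimp-1 went from 5918 ± 293 to 669 ± 26.1 normalized counts in wild type and from 1187 ± 467 to 1163 ± 245 in EcR-RNAi (n = 2 each). Without replicates 1 and 2 of EcR-RNAi at -6 h, Aldh was at 3.48 and 4.83, Edg91 at 4.68 and 6.83, Jon65Aiii at -7.73 and -9.78, yip7 at -6.15 and -7.54, and Jon65Aiv at -5.72 and -7.62. Without wild-type replicates 1 and 2, Osi3 was at -6.74 and -5.33 (-6 h) and yip7 at -6.18 and -7.50 (+6 h).

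Of 14 apical matrix genes tested, 2 had a positive and 10 a negative interaction (2 and 11 adjusted over the list alone). Their median of -2.24 had a camera padj = 1.7e-05 (adjusted p = 0.104 with an estimated correlation). They were led by nyo (-3.21 ± 0.18, limma padj = 9.7e-07) and f (-3.25 ± 0.18, padj = 9.7e-07). Of 19 extracellular matrix genes tested, 0 had a positive and 13 a negative interaction (1 and 13 adjusted over the list alone). Their median of -0.82 had a camera padj = 3.4e-05 (adjusted p = 0.104 with an estimated correlation). Np (-3.09 ± 0.19, limma padj = 1.6e-06) and Sb (-1.85 ± 0.18, padj = 4.1e-05) led. Of 12 glycolysis genes tested, 0 had a positive and 10 a negative interaction (0 and 11 adjusted over the list alone). Their median of -1.24 had a camera padj = 3.3e-06 (adjusted p = 0.386 with an estimated correlation). Examples were ImpL3 (-2.48 ± 0.20, limma padj = 1.1e-05) and Pglym78 (-1.79 ± 0.18, padj = 5.1e-05). Of 39 cell cycle genes tested, 26 had a positive and 0 a negative interaction (26 and 0 adjusted over the list alone). Their median of 1.09 had a camera padj = 1.2e-11 (adjusted p = 0.122 with an estimated correlation). They were headed by fzy (1.73 ± 0.16, limma padj = 3.1e-05) and mus209 (1.31 ± 0.14, padj = 7.2e-05). Camera also called other ecdysone-inducible (2 of 14 positive, 8 negative, median -1.09, camera padj = 0.0194), JNK and stress (0 of 11 positive, 5 negative, median -0.34, camera padj = 0.0199), striated muscle (0 of 7 positive, 3 negative, median -1.19, camera padj = 0.00732) and mitochondrial ribosomal genes (3 of 72 positive, 0 negative, median 0.21, camera padj = 0.0199). With an estimated correlation they had adjusted p = 0.386 to 0.733, and 2, 0, 0 and 0 members were positive and 8, 5, 6 and 0 negative adjusted over the list alone. The JNK phosphatase gene puc was at -1.41 ± 0.14, limma padj = 4.9e-05. Of 10 tracheal genes, 1 had a positive and 4 a negative interaction (the same over the list alone). Their median of -0.15 (camera padj = 0.29) turned positive with upper-quartile and quantile scaling.

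Of 23 ecdysone-response transcription factors and early genes tested, 8 had a positive and 7 a negative interaction (9 and 7 adjusted over the list alone). Their median of 0.24 had a camera padj = 0.697. Their mean, at -0.05, had the other sign. Besides that of EcR, negative interactions were those of ftz-f1 (-3.25 ± 0.41, limma padj = 0.00212), Cyp18a1 (-3.16 ± 0.48, padj = 0.00438), E23 (-2.26 ± 0.15, padj = 2.9e-06), vri (-1.92 ± 0.25, padj = 5.1e-04) and usp (-0.65 ± 0.16, padj = 0.0119, lost at padj = 0.111). Positive ones were those of let-7-C (1.96 ± 0.27, limma padj = 3.7e-04), Hr46 (1.32 ± 0.18, padj = 3.1e-04), Kr-h1 (1.05 ± 0.19, padj = 0.00186), Hr39 (1.03 ± 0.17, padj = 0.00141) and crol (0.61 ± 0.19, padj = 0.0339, lost at padj = 0.134). Among chaperone genes Hsp68 was at -5.62 ± 0.26, limma padj = 5.0e-07 and Hsp26 at -1.13 ± 0.18, padj = 8.3e-04. Of 57 cuticle and chitin genes tested, 6 had a positive and 11 a negative interaction (6 and 11 adjusted over the list alone). Their median of -0.31 had a camera padj = 0.697. That median turned positive with quantile scaling, and the mean was 0.07.

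At -6 h, 17 of 57 cuticle, 6 of 12 glycolysis, 6 of 11 JNK and stress and 6 of 8 fat body genes were higher in EcR-RNAi than in wild type, and 9 of 23 ecdysone-response genes were lower. Camera called the former 4 lists with the preset correlation but none with an estimated one, and not the ecdysone-response list. The largest increases were those of w, an eye pigment transporter gene often carried by transgenes (7.83 ± 0.17, limma padj = 5.8e-10), CHKov1 (6.77 ± 0.40, padj = 1.5e-04), and mthl8, with 1 read in wild type and a ratio of 418 (95% counting interval 74.5 to 16552). The gut protease gene Jon65Aiv was also higher (6.67 ± 0.75, limma padj = 2.3e-04, lost at padj = 0.121, by edgeR). Jon65Aiii had 1 read in wild type and a ratio of 712 (95% counting interval 127 to 28179.9), and yip7 3 reads and a ratio of 147 (95% counting interval 50.1 to 718). Ir68a, an ionotropic receptor gene with 2 reads in EcR-RNAi, had a ratio of 65.8 (95% counting interval 17.9 to 549) for wild type over EcR-RNAi. Lower genes were GstE1, a glutathione transferase gene (-3.60 ± 0.20, limma padj = 3.9e-06), PICK1 (-2.70 ± 0.47, padj = 0.0032), nrm (-2.39 ± 0.39, padj = 0.00856, lost at padj = 0.0713), Blimp-1 (-2.37 ± 0.27, padj = 0.00227) and snoRNA:Psi28S-1837b (-1.95 ± 0.35, padj = 0.0042, lost at padj = 0.0589). In all, 584 genes were higher and 261 lower (10.9% of those tested). Higher genes numbered 354 without replicate 2 of wild type at -6 h. Lower genes numbered 100 without that library, 146 without replicate 2 and 562 without replicate 1 of EcR-RNAi at -6 h, and 595 without both libraries with raised roX1. Without replicates 1 and 2 of EcR-RNAi at -6 h, Jon65Aiv was at 5.72 and 7.62, Jon65Aiii at 6.47 and 8.52, and yip7 at 5.49 and 6.88.

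Of 23 ecdysone-response transcription factors and early genes tested, 4 were higher and 9 lower (6 and 10 adjusted over the list alone). Their median of -0.13 had a camera padj = 0.0903. Lower were the nuclear receptor genes Hr46 (-1.36 ± 0.13, limma padj = 8.2e-05), Eip78C (-1.23 ± 0.14, padj = 2.7e-04), Eip75B (-0.98 ± 0.12, padj = 4.6e-04), Hr4 (-0.88 ± 0.13, padj = 9.8e-04) and Hr39 (-0.71 ± 0.12, padj = 0.00341). The Ets factor gene Eip74EF (-0.86 ± 0.12, limma padj = 8.7e-04) and let-7-C (-0.97 ± 0.19, padj = 0.0072, lost at padj = 0.0806) were lower too. Higher were Cyp18a1 (2.15 ± 0.34, limma padj = 0.0111, lost at padj = 0.0869), ftz-f1 (2.02 ± 0.29, padj = 0.00753), Eip93F (1.67 ± 0.32, padj = 0.01, lost at padj = 0.0802) and E23 (1.15 ± 0.11, padj = 8.7e-05). Not called by limma were Hr38 at 1.76 ± 0.51, chinmo at 0.76 ± 0.35, vri at 0.50 ± 0.18, tai at -0.42 ± 0.15, br at -0.29 ± 0.21 and Smr at -0.13 ± 0.16. Alternatives called Hr38 (lowest padj = 0.0123), chinmo (0.00195), vri (0.0112), tai (0.00611) and br (0.0285). Nor were usp at 0.08 ± 0.11, Sox14 at 0.04 ± 0.16, Kr-h1 at -0.02 ± 0.13 and crol at 0.07 ± 0.13, which turned negative with quantile scaling.

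Of 57 cuticle and chitin genes tested, 17 were higher and 3 lower (30 and 3 adjusted over the list alone). Their median of 1.39 had a camera padj = 6.2e-12 (adjusted p = 0.493 with an estimated correlation). Cpr31A (3.22 ± 0.22, limma padj = 1.5e-05) and obst-A (1.75 ± 0.17, padj = 1.4e-04) were higher. Of 8 fat body genes tested, 6 were higher and 0 lower (8 and 0 adjusted over the list alone). Their median of 3.06 had a camera padj = 4.0e-07 (adjusted p = 0.479 with an estimated correlation). The larval serum protein genes Lsp1gamma (3.47 ± 0.38, limma padj = 6.6e-04) and Lsp1alpha (4.07 ± 0.56, padj = 0.00201, lost at padj = 0.0703) were higher, the latter at 4.97 and 3.17 without wild-type replicates 1 and 2 at -6 h. Of 11 JNK and stress genes tested, 6 were higher and 1 lower (7 and 1 adjusted over the list alone). Their median of 0.59 had a camera padj = 0.00191 (adjusted p = 0.479 with an estimated correlation). Gadd45 (2.08 ± 0.15, limma padj = 1.5e-05) and Ets21C (2.18 ± 0.27, padj = 4.6e-04) were higher. Of 12 glycolysis genes tested, 6 were higher and 0 lower (8 and 1 adjusted over the list alone). Their median of 0.48 had a camera padj = 0.00116 (adjusted p = 0.51 with an estimated correlation). Ald (1.09 ± 0.15, limma padj = 6.7e-04) and the enolase gene Eno (0.61 ± 0.12, padj = 0.00724, lost at padj = 0.0778) were higher. Camera also called apical matrix (7 of 14 higher, 3 lower, median 0.41, camera padj = 0.0391), extracellular matrix (5 of 19 higher, 0 lower, median 0.18, camera padj = 0.0105), striated muscle (4 of 7 higher, 0 lower, median 0.60, camera padj = 0.00233), melanin and sclerotization (3 of 10 higher, 0 lower, median 0.79, camera padj = 0.00191), cytosolic ribosomal (8 of 87 higher, 0 lower, median 0.30, camera padj = 9.6e-07) and actomyosin and junction genes (0 of 26 higher, 2 lower, median -0.18, camera padj = 0.00233). With an estimated correlation they had adjusted p = 0.479 to 0.606, and 7, 5, 4, 5, 8 and 0 members were higher and 4, 0, 0, 0, 0 and 2 lower adjusted over the list alone.

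Of 35 wing patterning genes tested, 1 was higher and 3 lower (1 and 3 adjusted over the list alone). Their median of -0.22 had a camera padj = 0.00262 (adjusted p = 0.697 with an estimated correlation). Among them, aos (-0.58 ± 0.13, limma padj = 0.0186, lost at padj = 0.0888) and ap (-0.51 ± 0.12, padj = 0.0235, lost at padj = 0.155) were lower. Of 39 cell cycle genes tested, 1 was higher and 2 lower (1 and 2 adjusted over the list alone). Their median of -0.19 had a camera padj = 0.0152 (adjusted p = 0.561 with an estimated correlation). Of these, RnrL was lower (-0.53 ± 0.11, limma padj = 0.0122, lost at padj = 0.105) and trbl higher (0.55 ± 0.11, padj = 0.01, lost at padj = 0.074). The chaperone genes Hsp68 (5.13 ± 0.18, limma padj = 6.6e-08) and DnaJ-1 (1.46 ± 0.24, padj = 0.00848, lost at padj = 0.0653) were higher. Hsp68 was at 36 ± 1.1 normalized counts in wild type and 1295 ± 123 in EcR-RNAi at -6 h, and at 90.4 ± 9.2 and 64.6 ± 14.7 at +6 h (n = 2 each).

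At +6 h, 10 of 14 apical matrix, 12 of 19 extracellular matrix, 9 of 12 glycolysis and 9 of 14 other ecdysone-inducible genes were lower in EcR-RNAi than in wild type, and 29 of 39 cell cycle and 24 of 57 cuticle genes were higher. None of these lists passed camera with an estimated correlation. The largest increases were those of the cuticle genes Ccp84Ab (8.31 ± 1.04, limma padj = 0.00157), Cpr78Cc (8.01 ± 1.64, padj = 0.0178, lost at padj = 0.0747), Ccp84Aa (7.62 ± 0.77, padj = 0.00107) and Edg91 (7.33 ± 0.61, padj = 4.9e-05), and of w (7.49 ± 0.17, padj = 9.5e-10). The gene mthl8 had no read in wild type at +6 h and was at least 85.7-fold higher. The synapsin gene Syn, with 1 read in EcR-RNAi, had a ratio of 632 (95% counting interval 113 to 25012) for wild type over EcR-RNAi. Lower were Osi3 (-5.41 ± 0.44, limma padj = 5.9e-06), the wing hair gene mwh (-4.52 ± 0.20, padj = 1.5e-07), Esp (-4.21 ± 0.66, padj = 4.6e-04), the protease gene Corin (-3.93 ± 0.51, padj = 1.2e-04) and the myosin gene ninaC (-3.89 ± 0.38, padj = 1.7e-05). In all, 1653 genes were higher and 1680 lower (42.9% of those tested). Of the calls, 49.6% were increases, against 64.4% with upper-quartile scaling, which shifted the median of all genes by 0.15. Higher genes numbered 1094 without replicate 2 of EcR-RNAi at +6 h. Without wild-type replicates 1 and 2 at +6 h, Cpr78Cc was at 9.42 and 6.60 and Esp at -4.85 and -3.58.

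Of 23 ecdysone-response transcription factors and early genes tested, 5 were higher and 10 lower (7 and 11 adjusted over the list alone). Their median of -0.35 had a camera padj = 0.405. Lower besides EcR were E23 (-1.11 ± 0.11, limma padj = 2.0e-05), vri (-1.42 ± 0.18, padj = 1.9e-04), Hr4 (-0.85 ± 0.13, padj = 3.0e-04), Eip74EF (-0.62 ± 0.12, padj = 0.00157), Eip78C (-0.73 ± 0.14, padj = 0.00177) and usp (-0.57 ± 0.11, padj = 0.00216). Higher were the transcription factor genes chinmo (2.54 ± 0.35, limma padj = 0.0014), Hr38 (2.29 ± 0.51, padj = 0.00406), Kr-h1 (1.03 ± 0.13, padj = 1.1e-04) and crol (0.68 ± 0.13, padj = 0.00184), and let-7-C (0.98 ± 0.19, padj = 0.00172). Not called by limma were Cyp18a1 at -1.005 ± 0.34, Blimp-1 at 0.78 ± 0.27, Eip93F at 0.58 ± 0.32, Hr39 at 0.32 ± 0.12, tai at -0.33 ± 0.15 and Smr at 0.10 ± 0.16. Alternatives called Cyp18a1 (lowest padj = 8.1e-06), Blimp-1 (2.6e-04), Eip93F (0.0219), Hr39 (0.00375), tai (0.0246) and Smr (0.0382), the first pair also by edgeR and DESeq2. Nor were br at -0.35 ± 0.21 and Hr46 at -0.04 ± 0.13, both positive with quantile scaling. Of 14 other ecdysone-inducible genes tested, 2 were higher and 9 lower (2 and 9 adjusted over the list alone). Their median of -1.197 had a camera padj = 0.016 (adjusted p = 0.458 with an estimated correlation). ImpE1 (-2.60 ± 0.14, limma padj = 2.8e-07), Sb (-1.75 ± 0.13, padj = 2.4e-06) and ImpL3 (-1.80 ± 0.14, padj = 5.2e-06) were lower and ImpE3 higher (1.55 ± 0.14, padj = 1.4e-05).

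Of 14 apical matrix genes tested, 3 were higher and 10 lower (3 and 10 adjusted over the list alone). Their median of -1.93 had a camera padj = 0.00172 (adjusted p = 0.19 with an estimated correlation). The level of nyo was 29139 ± 3637 normalized counts in wild type and 4553 ± 286 in EcR-RNAi (n = 2 each; -2.67 ± 0.13, limma padj = 1.5e-07). Of 19 extracellular matrix genes tested, 1 was higher and 12 lower (1 and 12 adjusted over the list alone). Their median of -0.56 had a camera padj = 9.1e-04 (adjusted p = 0.19 with an estimated correlation). Np was at -2.24 ± 0.14, limma padj = 7.8e-07. Of 12 glycolysis genes tested, 1 was higher and 9 lower (1 and 9 adjusted over the list alone). Their median of -0.84 had a camera padj = 9.1e-04 (adjusted p = 0.721 with an estimated correlation). The phosphofructokinase gene Pfk was lower (-1.31 ± 0.11, limma padj = 5.9e-06). Of 39 cell cycle genes tested, 29 were higher and 1 lower (32 and 1 adjusted over the list alone). Their median of 0.90 had a camera padj = 6.5e-09 (adjusted p = 0.19 with an estimated correlation). The cyclin gene CycB3 (1.63 ± 0.11, limma padj = 1.7e-06) and fzy (1.55 ± 0.12, padj = 3.0e-06) were higher. Of 57 cuticle and chitin genes tested, 24 were higher and 6 lower (24 and 6 adjusted over the list alone). Their median of 1.06 had a camera padj = 8.4e-04 (adjusted p = 0.804 with an estimated correlation). Cpr31A was higher (2.35 ± 0.22, limma padj = 1.6e-05) and Cht5 lower (-2.14 ± 0.15, padj = 1.8e-06). Camera also called actomyosin and junction (1 of 26 higher, 14 lower, median -0.35, camera padj = 0.016), mitochondrial ribosomal (12 of 72 higher, 0 lower, median 0.27, camera padj = 0.02) and fat body genes (3 of 8 higher, 0 lower, median 1.305, camera padj = 0.0341). With an estimated correlation they had adjusted p = 0.804, and 1, 9 and 3 members were higher and 14, 0 and 0 lower adjusted over the list alone. The myosin gene sqh was lower (-0.74 ± 0.13, limma padj = 8.7e-04) and Lsp1gamma higher (2.65 ± 0.38, padj = 6.7e-04). Among cell-type lists that did not pass camera, 1 of 10 tracheal genes was higher and 5 lower (median -0.22, mean -0.61, camera padj = 0.0819), 1 of 6 haemocyte genes was higher and 3 lower (median -0.49, mean -0.17, camera padj = 0.405), and 1 of 7 striated muscle genes was higher and 5 lower (median -0.61, mean -0.39, camera padj = 0.405). Adjusted over the list alone, 1, 1 and 2 were higher and 5, 3 and 5 lower. Of genes in other lists that did not pass, Gadd45 was higher (2.39 ± 0.15, limma padj = 7.8e-07) and puc (-0.84 ± 0.10, padj = 7.4e-05), aos (-1.29 ± 0.13, padj = 2.9e-05) and stan, a planar polarity gene (-0.94 ± 0.11, padj = 5.8e-05), were lower.

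**Figure D3:**
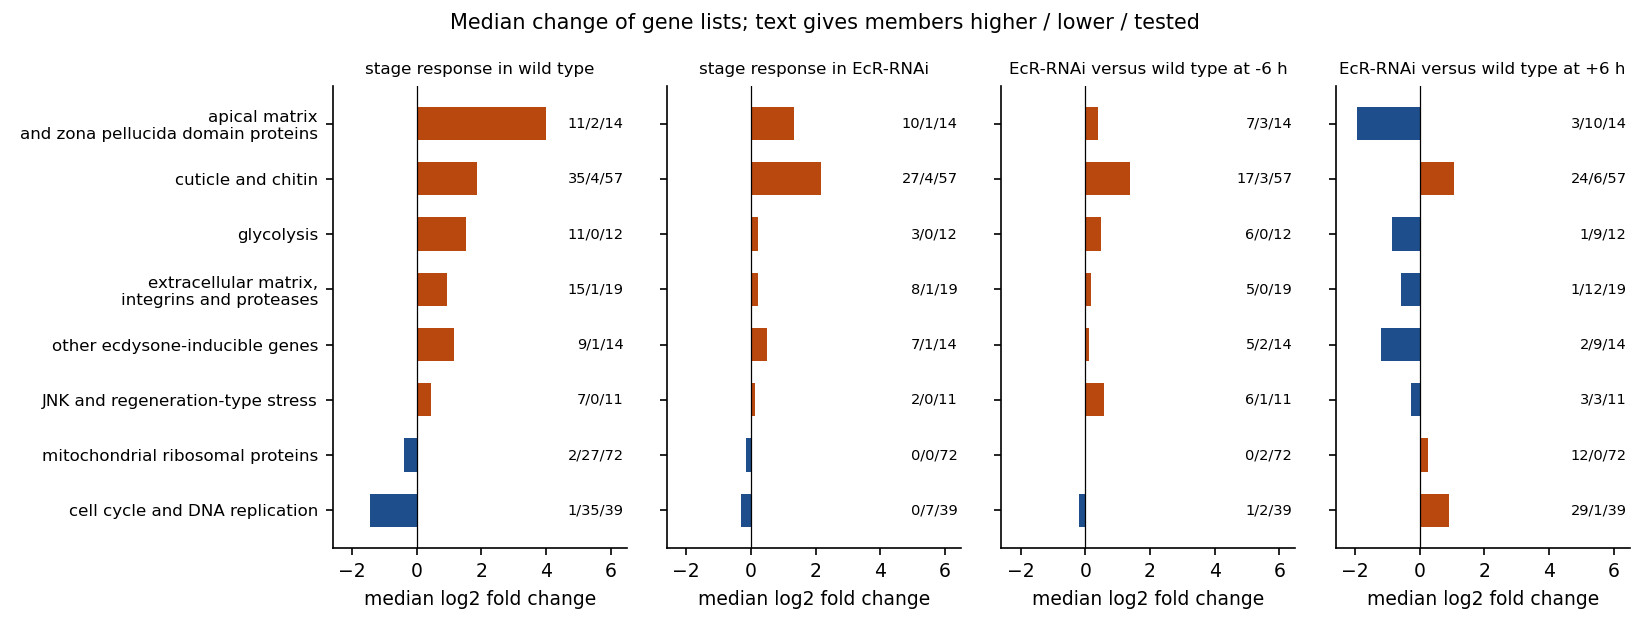
Median log2 fold change (horizontal axis) of 8 gene lists in the stage response of wild type and of EcR-RNAi and in EcR-RNAi against wild type at -6 h and +6 h, with the numbers of members higher, lower and tested at the right. The cell cycle list is at -1.44, -0.30, -0.19 and 0.90, and the sign of the bar changes under other scalings for mitochondrial ribosomal proteins at -6 h (TMM-like) and for JNK and stress genes in the EcR-RNAi stage response (upper-quartile and quantile).

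Of the 1680 genes lower in EcR-RNAi at +6 h, 1387 (82.6%) were among those that rose in wild type, including nyo, Np, ImpL3 and E23, where independent lists would share 488. Of the 1653 higher genes, 1299 (78.6%) fell in wild type, including fzy and mus209 (441 for independent lists). Of the 584 genes higher at -6 h, 406 (69.5%) rose with stage in wild type, including ftz-f1 and E23 (170 for independent lists). Of the 261 lower genes, 85 fell with stage, including Blimp-1 and let-7-C (69.7 for independent lists), and 79 rose (75.8). The 406 became 251 and the 85 became 26 without replicate 2 of wild type at -6 h. The 85 also became 43 without replicate 2 and 170 without replicate 1 of EcR-RNAi at -6 h, and 172 without both libraries with raised roX1. Fold changes of the wild-type stage response and of genotype at +6 h correlated across genes with r = -0.58, against -0.53 in simulations of unchanged groups that share libraries. The covariance was -0.88 against -0.037, and 20.96% of genes had the same sign against 32.3%. For genotype at -6 h, r was 0.46 against 0.46, the covariance 0.52 against 0.033, and the share of the same sign 59.6% against 66.1%. As no group differed in these simulations, few genes could be called in them. Their shared calls, at most 1, therefore do not show how much shared libraries add to the overlaps.

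Of the 943 genes that rose with stage in EcR-RNAi, 866 (91.8%) also rose in wild type, including E23, ftz-f1 and nyo (274 for independent lists), and of the 302 that fell, 256 (84.8%) also fell (80.6 for independent lists). Between stages, EcR-RNAi had 204 genes higher at both, such as w, mthl8 and Gadd45 (124 for independent lists), and 151 lower at both, such as Hr4 and Eip78C (56.4 for independent lists). Another 207, such as E23, were higher at -6 h and lower at +6 h (126 for independent lists). The 204 became 125 without replicate 2 of EcR-RNAi at +6 h. The 151 became 70 without replicate 2 of wild type at -6 h and 237 without replicate 1 of EcR-RNAi at -6 h. The genotype effects at both stages correlated with r = 0.27 and rho = 0.14 across genes.

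Markers of other cell types were read in all libraries. Of 7 striated muscle genes tested, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Their median of 1.80 had a camera padj = 0.00334 (adjusted p = 0.347 with an estimated correlation). The titin gene sls was at 1.80 ± 0.11, limma padj = 1.2e-07, in the wild-type stage response. In the same comparison, of 10 adult muscle precursor genes tested, 5 rose and 2 fell (5 and 2 adjusted over the list alone). Their median was 0.50, with Him (1.47 ± 0.14, limma padj = 5.6e-06) and twi (1.03 ± 0.13, padj = 5.7e-05) higher. Of 10 tracheal genes tested, 4 rose and 2 fell (4 and 2 adjusted over the list alone). Their median of 0.14 turned negative with upper-quartile and quantile scaling. Among them mtg rose (3.57 ± 0.10, limma padj = 4.6e-10) and pio fell (-1.67 ± 0.10, padj = 1.5e-07). Of 6 haemocyte genes tested, 2 rose and 2 fell (2 and 2 adjusted over the list alone). The median was 0.53 and the mean -0.03. Of 6 neuronal genes tested, 2 rose and 0 fell (2 and 0 adjusted over the list alone). The median of 0.66 turned negative with quantile scaling. Of 9 genes of other discs tested, 2 rose and 4 fell (2 and 4 adjusted over the list alone). The median was -0.13 and the mean 0.10, with eya (1.06 ± 0.15, limma padj = 1.0e-04) and so (0.87 ± 0.14, padj = 2.4e-04) higher. Of 8 fat body genes tested, 1 rose and 1 fell (0 and 0 adjusted over the list alone). The median of 0.08 turned negative with upper-quartile and quantile scaling, and the mean was -0.09.

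In the EcR-RNAi stage response, of 8 fat body genes tested, 0 rose and 2 fell (0 and 3 adjusted over the list alone). Their median of -1.84 had a camera padj = 0.00203 (adjusted p = 0.49 with an estimated correlation). Of 9 genes tested of the leg, eye and notum list, 0 rose and 3 fell (0 and 4 adjusted over the list alone). Their median of -0.47 had a camera padj = 0.0107 (adjusted p = 0.44 with an estimated correlation). Camera did not call adult muscle precursors (3 of 10 rose, 0 fell, median 0.34), tracheal genes (3 of 10 rose, 1 fell, median 0.06), haemocyte genes (2 of 6 rose, 1 fell, median -0.36) or striated muscle (3 of 7 rose, 0 fell, median 0.53). Adjusted over the list alone, 4, 4, 2 and 4 rose and 1, 1, 1 and 1 fell. The tracheal median turned negative with upper-quartile and quantile scaling. Fbp1, the fat body gene with the highest mean, was at 134 ± 73.9 and 169 ± 60.0 normalized counts in wild type at -6 h and +6 h and at 816 ± 687 and 229.6 ± 18.5 in EcR-RNAi (n = 2 each). At -6 h the gut proteases Jon65Aiii, Jon65Aiv, yip7 and Jon25Bi summed to 1375 and 371 in EcR-RNAi, against at most 4.20 in any other library. Male X dosage compensation genes had no called member in any of the 5 comparisons (0 by limma, also 0 adjusted over the list alone). The noncoding RNA roX1, which belongs to that complex, was at 443 in replicate 2 of wild type at +6 h and 342 in replicate 1 of EcR-RNAi at -6 h. The other 6 libraries had 14.7 to 32.0, and all 8 are labelled female. Of 3 transgene and background markers tested, w was at 16.4 and 17.3 in wild type and 3903 and 3305 in EcR-RNAi. Their median and mean differ in sign between genotypes, at -6 h (-0.30 and 2.35) and at +6 h (-0.19 and 2.34, the median positive with quantile scaling).

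**Figure D4:**
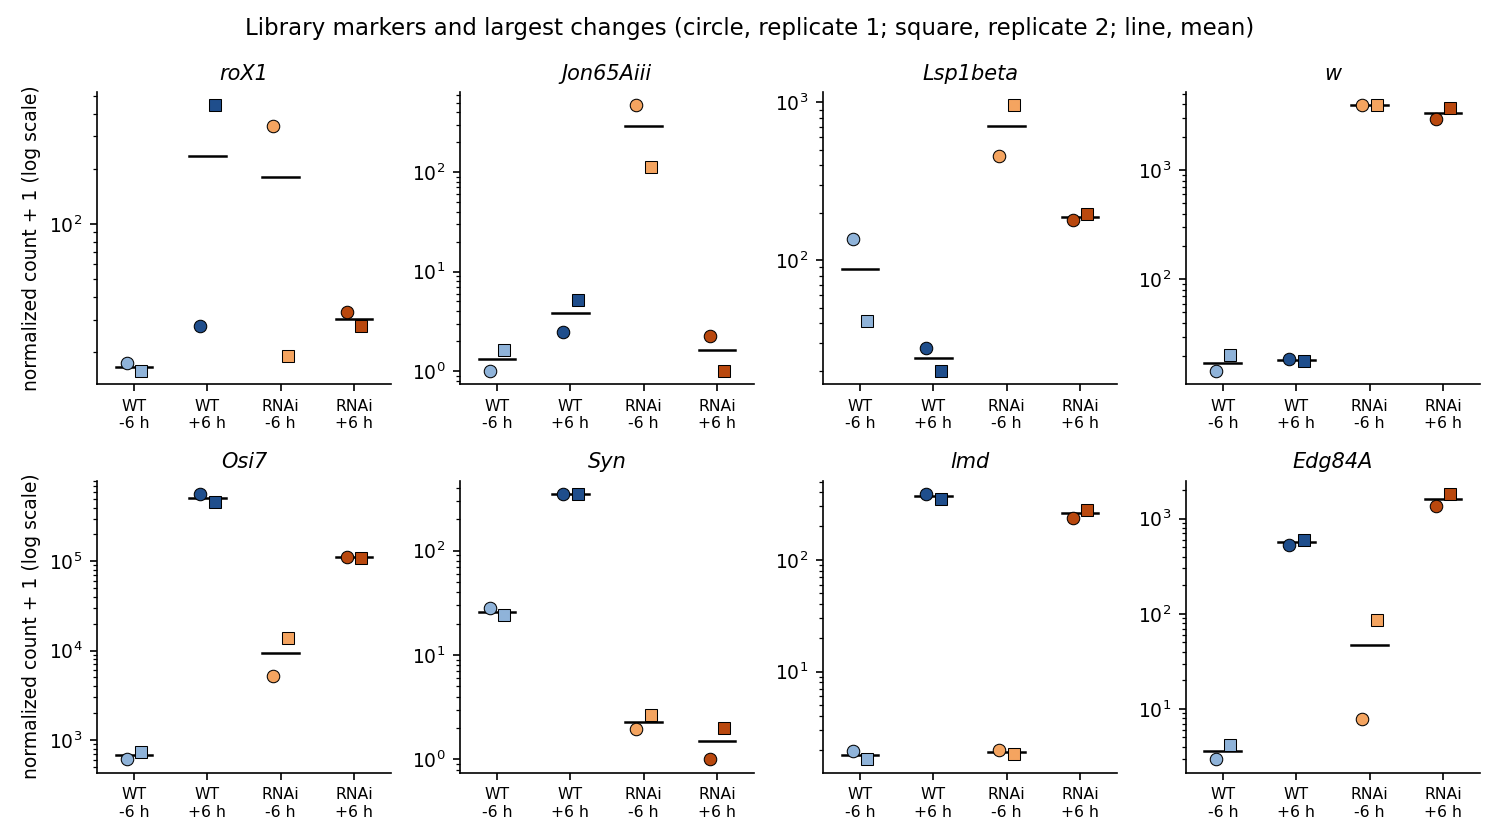
Normalized counts plus 1 on a log axis for roX1, Jon65Aiii, Lsp1beta, w, Osi7, Syn, lmd and Edg84A in the 8 RNA libraries, with circles for replicate 1, squares for replicate 2 and lines for group means. roX1 stands at 443 in wild type at +6 h replicate 2 and 342 in EcR-RNAi at -6 h replicate 1, above the 14.7 to 32.0 of the other libraries.

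CUT&RUN gave 4965 EcR peaks at -6 h and 1210 at +6 h, with a median width of 175 and 142 bp. Of the peaks at -6 h, 781 (15.7%, Wilson 95% interval 14.7 to 16.8%) overlapped a peak at +6 h by at least 1 bp. Of those at +6 h, 799 (66.0%, 63.3 to 68.6%) overlapped a peak at -6 h. With overlap over 50% of each peak the shares were 7.73% and 31.7%. After circular shifts along each arm, 22.6 and 22.3 peaks overlapped on average and at most 48 and 47. Shared peaks had higher median scores (336 against 67 at -6 h, 123 against 44 at +6 h). They were wider (355 against 157 bp, 172 against 102 bp), but wide peaks overlap more easily. Each permutation p was 1e-05, the minimum (adjusted p = 1e-05 over 6 tests), with peaks taken as independent. In the 20% of peaks with the highest scores, 53.3% at -6 h and 91.7% at +6 h overlapped the other stage, and in the lowest 20%, 3.22% and 32.6%. The lists differ in length and were called per stage, so their numbers do not show a change in binding.

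The 5 highest-scoring peaks at -6 h all lay on chromosome arm 3L (dm3): 5614735 to 5616164 (score 6238), 18005849 to 18007018 (score 5458), 18000282 to 18001448 (score 4972), 5620501 to 5621694 (score 4889) and 17957579 to 17959824 (score 4319). At +6 h they were 3L 5614846 to 5615531 (score 4114), 3R 9615440 to 9616442 (score 3979), 3L 17957579 to 17959695 (score 3621), 3L 18006004 to 18007004 (score 3478) and 3L 5626972 to 5627675 (score 3353). Each of these 10 peaks overlapped a peak of the other stage. The 100 kb window with the most peaks, singled out after the values were seen, was 3L 17900001 to 18000000, with 78 peaks at -6 h and 45 at +6 h.

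**Figure D5:**
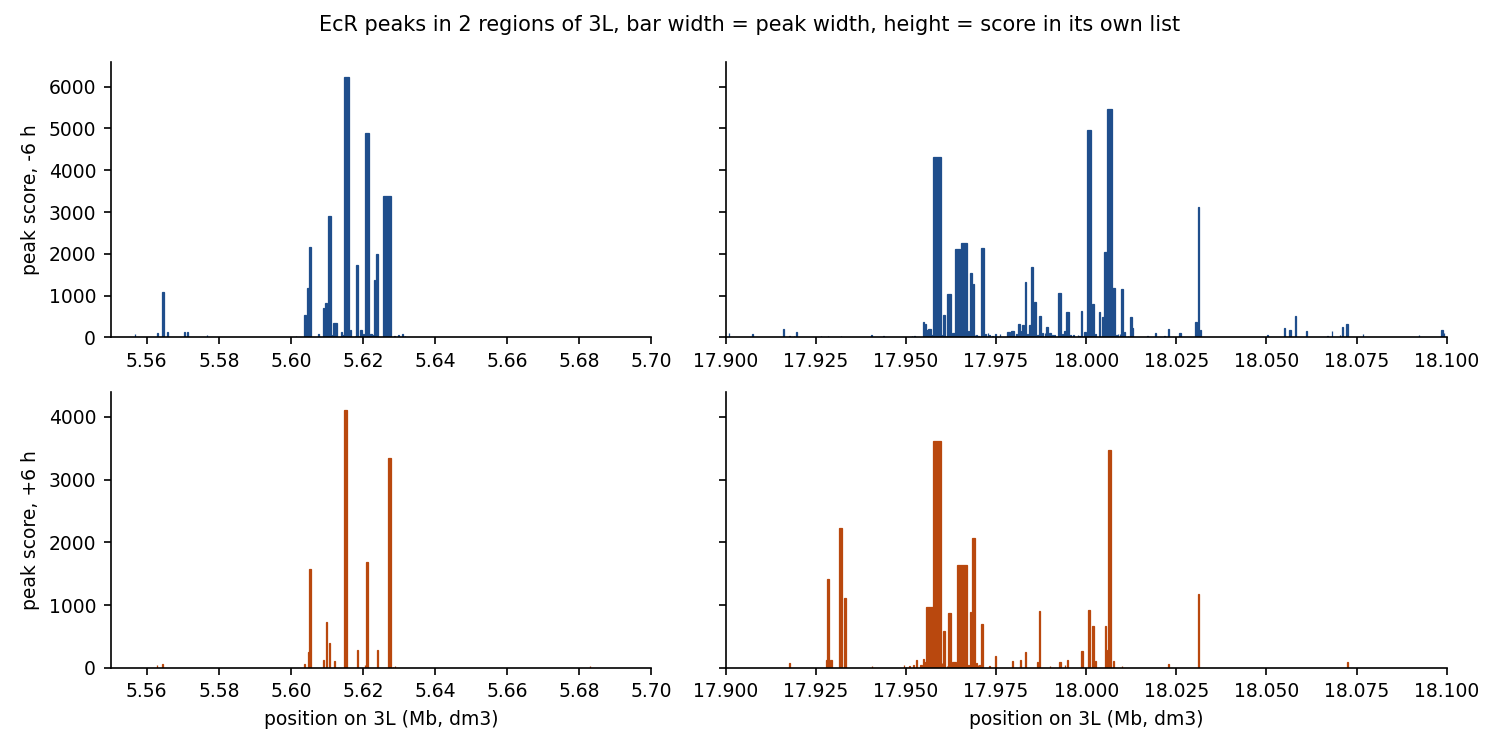
EcR peaks at -6 h and +6 h in 2 stretches of arm 3L (position in Mb, dm3), with bar width equal to peak width and bar height equal to the authors' score within each list. The highest bars are those at 5614735 to 5616164 (score 6238 at -6 h) and 5614846 to 5615531 (score 4114 at +6 h).

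In the authors' deposited table, given as -6 h over +6 h or wild type over EcR-RNAi, EcR had a log2 fold change of -1.60 for stage in wild type and -0.54 in EcR-RNAi, and of 0.48 for genotype at -6 h and 1.55 at +6 h. At an adjusted p under 0.05 the authors' deposited table calls 3700, 1027, 767 and 2606 genes for stage in wild type, stage in EcR-RNAi, genotype at -6 h and genotype at +6 h. Of these, 3510, 933, 624 and 2499 were also called by limma, all in the same direction. Log2 fold changes of the authors' deposited table and limma correlated with r of 0.989 to 0.994 in size across genes.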

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

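The tests of a genotype change of gut and fat body genes, of genes absent from a mixture, and of older wings in a pool, and the list of further midgut enzymes, were chosen after the result was seen.

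The genotype by stage interaction marked these results as differences between groups: 905 positive and 1197 negative interactions, and interaction values of 5.75 for Edg91, 4.16 for Aldh, 3.16 for Blimp-1, 3.03 for fru, 2.93 for mp, 2.75 for LRP1, -8.76 for Jon65Aiii, -7.06 for tx, -6.84 for yip7, -6.67 for Jon65Aiv, -6.19 for ImpL1 and -6.03 for Osi3. The median interaction was -2.24 for apical matrix genes, -1.24 for glycolysis, -1.19 for striated muscle, -1.09 for other ecdysone-inducible genes, -0.82 for the extracellular matrix, -0.34 for JNK and stress genes, 0.21 for mitochondrial ribosomal proteins and 1.09 for cell cycle genes. Camera with an estimated correlation called 0 lists in the interaction, and the interaction calls of Jon65Aiii, yip7 and Jon65Aiv ended with edgeR (adjusted p = 0.178, 0.292 and 1).

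Gut proteases (Jon65Aiii, Jon65Aiv, yip7 and Jon25Bi) summed to 1375 and 371 in the EcR-RNAi libraries at -6 h, and fat body genes to 2220 and 5074, against 774 and 350 in wild type, while salivary glue genes ran the other way (2.92 and 8.19 against 125 and 17.9). If other larval tissue was carried over with the wings, further midgut enzymes should peak in the library with most Jon65Aiii; of 24 such genes only 3 had at least 5 reads, and 66.7% of them did, which is too few to tell. For a change of these genes in the wing with genotype, the lowest ratio of either list over wild type was 2.87, but this restates the pattern and decides nothing. An earlier test, on the median log2 ratio of replicate 1 over 2 (1.98 for the proteases and -0.94 for fat body genes), had gone against a genotype change and was set aside after its result was seen, because such a change does not forbid variation between replicates. No value at hand decides between carry-over and a genotype change, and strain background was not tested.

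Of the 2259 genes that rose with stage in wild type, 406 (18.0%) were called higher and 79 lower in EcR-RNAi at -6 h (median 0.15 over all 2259), and the slope of this genotype effect on the stage response was 0.28 for genes that rose and 0.059 for genes that fell. With separate wild-type libraries in each axis the slope of lower genes was 0.0418 times that of higher ones. A later age of all wings need not move both sets alike, so it stays open. Reads of a +6 h library mixed in should add each gene in the same share: 78.2% of genes lay within 2-fold of the median share, between limits set in advance, but 5 abundant +6 h genes lay far below their share, such as lmd with 0.82 in replicate 2 against 258 at +6 h, which argues against it. Some older wings in the pool could make replicates differ, and the slope in replicate 2 was 1.60 times that in replicate 1, which cannot decide. Effects of EcR loss and of strain background stay open and were not tested, as no control had the driver alone.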

How the results depend on the processing

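Leaving out libraries with raised roX1 and shifting peaks were chosen after the data were seen. Of 288 called values of named genes, 5775 of 5980 under alternatives kept direction and call (96.6%), 205 direction only, and 0 reversed. Most were picked for size or low p, so others may be less stable. Of 25 named values that were not called, 441 of 523 stayed so (84.3%), 60 were called in the same direction and 22 reversed, 3 of which were called with the other sign. Calls ended most often without replicates 1 and 2 of EcR-RNAi at +6 h (28 and 26) and replicate 2 of wild type at -6 h (23), and never with TMM-like scaling or a pseudocount of 5, nor for the 273 values kept by a minimum mean of 50.

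At a fold change of at least 2, genes higher and lower numbered 1237 and 859 in the wild-type stage response, 561 and 53 in the EcR-RNAi stage response, 317 and 78 for genotype at -6 h, 603 and 605 at +6 h, and 456 and 663 in the interaction. Fewer genes pass because the rule adds a limit. Upper-quartile scaling gave 3335 lower genes in wild type, 874 lower in EcR-RNAi and 1377 positive interactions, and quantile scaling 945 lower in EcR-RNAi. Upper-quartile scaling applies a single factor to each library. Quantile scaling moves genes by different amounts, and the cause of its 945 was not tested. DESeq2 gave 182 lower genes in EcR-RNAi, and leaving out the libraries with raised roX1 gave 595 lower genes at -6 h and a slope of 0.36 (0.41 with all), with causes that were not tested. With edgeR, genes rising and falling numbered 2182 and 2150 in wild type and 928 and 338 in EcR-RNAi, those higher and lower numbered 589 and 270 at -6 h and 1665 and 1634 at +6 h, and 959 and 1154 interactions were positive and negative.

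Leaving out single libraries, which leaves fewer samples, moved some counts by over 1.5 times. In the EcR-RNAi stage response, increases ranged from 506 to 967 and decreases from 96 to 318. For genotype, higher genes ranged from 354 to 697 and lower from 100 to 562 at -6 h, and higher from 1094 to 1708 at +6 h. Positive interactions ranged from 584 to 991. Genes higher with stage in wild type and in EcR-RNAi at -6 h ranged from 251 to 512, and genes lower in both from 26 to 170. Genes higher in EcR-RNAi at both stages ranged from 125 to 238 and genes lower at both from 70 to 237. At least 2-fold, these overlaps were 210, 15, 104 and 39, and 528 genes rose with stage and were lower in EcR-RNAi at +6 h while 386 did the opposite. Without the libraries with raised roX1, 172 genes fell with stage and were lower at -6 h.

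Camera with an estimated correlation called 0 lists in each of the 5 comparisons, against 10, 13, 12, 9 and 8 of 27 with the preset (wild-type stage, EcR-RNAi stage, genotype at -6 h and at +6 h, interaction). At an unadjusted p under 0.05 it had 3, 4, 2, 3 and 3, and fry called 15, 9, 9, 10 and 10. List medians that changed sign under a scaling numbered 8, 5, 2, 6 and 10.

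Genes that were not called changed sign in several alternatives. In the wild-type stage response, quantile scaling gave br -0.95 (limma padj = 0.0187), Eip75B -0.66 (padj = 2.8e-04) and Hr38 -0.47 (padj = 0.434). Eip75B was at -0.30 with upper-quartile scaling (limma padj = 0.0457), -0.012 with TMM-like scaling and -0.015 with edgeR. For genotype at -6 h, crol was at -0.079 with quantile scaling and -0.080 without the libraries with raised roX1. At +6 h, quantile scaling gave br 0.10 and Hr46 0.26, and upper-quartile scaling Hr46 0.11. Without single libraries, stage values in wild type ran from -0.19 to 0.066 for Eip74EF, -0.050 to 0.075 for Eip75B, and -0.17 to 0.0050 for Smr. At -6 h they ran from -0.094 to 0.061 for Kr-h1, -0.39 to 0.12 for Smr, -0.23 to 0.30 for Sox14, -0.62 to 0.031 for br, -0.080 to 0.22 for crol and -0.025 to 0.19 for usp, and at +6 h from -0.13 to 0.047 for Hr46. The cause was not tested.

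Replicate numbers do not pair the samples, with correlations of deviations between -0.148 and 0.129. With a block for the replicate number, calls higher and lower were 2260 and 2074, 915 and 271, 566 and 252, 1647 and 1679, and 889 and 1172. The block ended the calls of Ccp84Ad, Hr39 and Hr38 in the EcR-RNAi stage response (limma padj = 0.0840, 0.0516 and 0.0598).

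Of peaks at -6 h and +6 h, 15.7% and 66.0% overlapped the other stage. The shares were 7.73% and 31.7% when overlap had to cover 50% of each peak, 18.8% and 77.0% in the upper 50% of each list by score, 45.9% and 48.3% with the same number of top peaks from each list, and 0.455% and 1.85% after circular shifts. Longer lists allow more overlap. The minimum mean of 10 leaves 7775 genes to test, and at these depths the simulations recovered 29.9% of 1.5-fold changes in wild type and 2.99% in the interaction.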

Other observations

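The tests of roX levels by stage, genotype and male animals and the families formed by name prefix were chosen after the result was seen.

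Of 31 gene families formed by name prefix, Osi and Nup are given here. They had the lowest camera p in the wild-type stage response. Of 24 Osi genes, which encode Osiris transmembrane proteins, 13 passed the minimum mean, some through their level at +6 h alone, and all 13 rose, with a median of 6.57 (camera padj = 9.4e-08, adjusted p = 0.184 with an estimated correlation). In EcR-RNAi 10 rose with stage, 5 were higher than in wild type at -6 h (none lower) and 11 lower at +6 h, and 12 had a negative interaction. All 16 tested Nup genes, which encode nuclear pore proteins, fell in wild type (median -1.05, camera padj = 1.2e-06, adjusted p = 0.139 with an estimated correlation). In EcR-RNAi 5 fell with stage, and 14 were higher than in wild type at +6 h.

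The noncoding RNA roX1 was at 443 in replicate 2 of wild type at +6 h and 342 in replicate 1 of EcR-RNAi at -6 h, against 14.7 to 32.0 elsewhere, and roX2 at 54.5 and 28.3 against at most 1.49. Stage or genotype should raise both replicates, but the smaller ratio between replicates was 16.5, which argues against them. Carried-over larval tissue should raise midgut, salivary glue or fat body genes as well, and in wild type at +6 h the largest ratio of replicate 2 over 1 was 2.62, in the glue list near its floor. In EcR-RNAi at -6 h, midgut enzymes summed to 38.0 and 5.73 in replicates 1 and 2, as with carry-over. Glue and fat body genes were lower in replicate 1, so carry-over stays open and allows males. Male animals in the pool should raise roX2 too, and its lowest ratio over the other libraries was 19.0, which leaves males possible, though the labels say female and no other test was at hand.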
